A study of Homo sapiens with 2 samples.

How the data were processed

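RNA was measured in primary HUVECs from 2 groups, vehicle (water) and CXCL8 (10 ng/mL for 6 h after 12 h in medium without supplement), with 1 GEO sample in each. Total RNA was depleted of ribosomal RNA with Ribo-Zero, and libraries were made with the NEBNext Ultra kit, per the labels' protocols. Depletion of ribosomal RNA, in place of selection for poly(A), leaves small nucleolar and other non-coding RNAs in the libraries. The submitters' processing notes name cutadapt, TopHat2 2.0.11, Cufflinks 2.2.1 and the build hg19. The annotation, filters and strand setting are not given in the sources used here.

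The authors deposited 1 table with 1 value per gene and group. These values were taken as FPKM, fragments per kilobase of transcript and per fixed number of mapped fragments, since the deposited columns hold fractional values, sum to totals that differ between groups, and carry an identifier header of the kind Cuffdiff writes. No header names the unit. The labels speak of biological duplicates, and whether each value pools or averages them is not stated. The number of value columns left unmatched to a sample was 0. FPKM values of transcripts shorter than a sequenced fragment rest on few possible fragment positions, so small RNA genes can take very high values or 0. FPKM also divides by the total of mapped fragments, so a change in abundant small RNAs shifts all other genes.

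Genes on chromosome Y and XIST were left out. In the remaining 23522 genes, the ratio of each gene was log2((CXCL8 FPKM + 1) / (vehicle FPKM + 1)), and genes with an FPKM of at least 1 in at least 1 group were tested, 12162 in all. Without separate values for the duplicates no test across samples could be run, and no standard error or p-value is given. Genes were counted by size, at 2-fold for all genes and at 1.5-fold for list members, both on this log2 scale. Read-through genes are gene models that span neighbouring genes, of which 41 were tested, beside 180 small RNA genes.

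Each of 33 gene lists was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins of equal size. A list needed 5 measured members, and it was said to lie outside the range when it fell outside the central 95% of random lists, 2.5% on each side, which about 1 list in 20 does by chance. Random lists draw independent genes, whereas genes of a pathway vary together, so the percentile describes these 2 samples and is not a test of the treatment. Some lists share genes, such as VCAM1, DLL4, CTGF and GJA4. The lists, thresholds and counts were chosen before the data were examined.

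The rule for named genes was also chosen then. It took the 12 genes with the largest difference in each direction among tested genes without small RNA genes, CXCL8, CXCR1, CXCR2 and ACKR1, and up to 4 members with the largest absolute log2 ratio in each list described. It also took ACTB, GAPDH and B2M, the endothelial and niche genes KDR, CDH5, PECAM1, VWF, SELE, VCAM1, ICAM1, KITLG and CXCL12, and the 3 small RNA genes with the largest absolute log2 ratio. Since 9 of these 24 genes are read-through genes, the 15 largest differences in each direction among genes with at least 5 FPKM in both groups were added after the values were seen, without small RNA genes, RMRP, RPPH1 and read-through genes. Genes taken by these rules numbered 189 in all, of which 1 is not reported here. Also chosen after the values were seen were 5 lists: the GIMAP family, arterial and venous endothelial genes, snoRNA host genes and nuclear long non-coding RNAs.

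Relative depth was read from protein-coding genes below 0.5 FPKM in both groups. For those above 0 in a group, FPKM was multiplied by transcript length, and the first peak of these products was taken as 1 fragment. The peak in vehicle over the peak in CXCL8 gave the relative depth, although the genes used differ in part between the groups. Its range came from 200 bootstrap draws over the genes of each group. This estimate assumes that each column behaves as 1 library. It covers relative depth only, and no counting interval can be given for a gene.

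Alternatives fixed in advance were pseudocounts of 0.1 and 5, no expression filter or one of at least 5 FPKM in 1 group, centring on the median log2 ratio, upper-quartile scaling of nonzero values, leaving out small RNA genes, and the mean in place of the median of a list. Upper-quartile scaling was fixed in advance for counts and single genes and added for lists after the values were seen, as were the GC content and length correction, random lists without small RNA genes, lists without certain members, and counts with at least 5 FPKM in both groups or without read-through genes. Upper-quartile scaling used the nonzero genes of each group, with quartiles of 18.6 FPKM in vehicle and 15.6 in CXCL8, a ratio of 0.840. Over genes above 0 in both groups the ratio was 0.940, so part of this scaling comes from which genes are above 0 in the deeper sample.

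GC content and transcript length were taken by gene symbol from GENCODE release 29, which is on another build than the deposited table, and no coordinates are given. They were found for 92.5% of tested genes. Across 11082 genes the log2 ratio had a Spearman rho of −0.09 with GC content and 0.08 with length. The correction removed the median log2 ratio in each cell of a grid of 10 by 10 classes of GC content and length. The host gene of a small nucleolar or Cajal body RNA was the smallest tested mRNA or long non-coding gene that contains it on the same strand in the same annotation.

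The scripts were tested on simulated data made from the 12162 tested genes. Of genes changed 4-fold, 100% were recovered past 1.5-fold in the simulated direction, and of genes changed 2-fold, 97%. Of unchanged genes 1.84% passed 1.5-fold. The simulated noise was normal, with a spread per expression bin taken from the ratios of these same 2 groups without small RNA genes. It holds no separate variation between cultures, so these shares check the scripts and are not error rates for these samples. Unshifted random lists of 25 genes lay outside the range in 5% of 300 draws, and lists shifted by −0.2 lay below percentile 2.5 in 99.3%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.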

Results

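Gene expression was measured by RNA sequencing in primary human umbilical vein endothelial cells (HUVECs), which line the vein of the umbilical cord and are a common culture model of endothelium. Cells in 1 group received recombinant CXCL8, also called interleukin 8, a chemokine that signals through the receptors CXCR1 and CXCR2. It was given at 10 ng/mL for 6 h, after 12 h without growth supplement. Cells in the other group received water for the same time. The series concerns the action of CXCL8 and CXCR1 on the vascular niche in which blood stem and progenitor cells lodge, and this comparison addresses which endothelial transcripts differ after CXCL8.

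The labels describe duplicate cultures, but each group holds 1 GEO sample with 1 FPKM value per gene, and whether that value averages the duplicates is not stated. No spread between cultures could be calculated, so no difference below has a replicate check and no p-value is given. Of 23522 genes considered, 12162 reached an FPKM of 1 in at least 1 group. The FPKM values summed to 2350804 in vehicle and 1756653 in CXCL8, of which genes for small RNAs with RMRP and RPPH1 took 79.6% and 73.4%. Absolute depth is unknown from FPKM values. Low values taken to stand for 1 fragment gave the CXCL8 sample a depth 1.66 times that of vehicle, with a bootstrap range of 1.55 to 1.74. In vehicle 7552 genes were listed at 0 and in CXCL8 6184, and 1915 genes were listed at 0 in vehicle alone against 547 in CXCL8 alone.

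The transcriptomes of CXCL8-treated and vehicle-treated cells were close, and most of the genes that differed by 2-fold were small RNA genes. VCAM1, an adhesion molecule that binds leukocytes and blood progenitors, was lower after CXCL8 at 16.4 FPKM against 32.5 in vehicle, a log2 ratio of −0.95. HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1, was lower at 19.1 against 43.6 FPKM, a log2 ratio of −1.15. The matrix-associated genes CTGF and CYR61 were higher, at 462 against 247 FPKM and 174 against 107 FPKM. NF-kB target genes as a list lay below expression-matched random lists, and mitotic genes lay above them. All ratios are CXCL8 over vehicle on the log2(FPKM + 1) scale, which understates the change of low genes.

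Of the 12162 tested genes, 11651 (95.8%) differed by less than 1.5-fold. At least a 1.5-fold difference was found in 247 genes that were higher and 264 that were lower after CXCL8. At least a 2-fold difference was found in 35 higher and 91 lower genes, of which small RNA genes made up 14 and 69 and read-through genes, annotated across neighbouring genes, 5 and 7. Among 8249 genes with at least 5 FPKM in both groups and without small RNA genes, 98.7% stayed within 1.5-fold, 56 were higher and 52 lower by 1.5-fold, and 2 were higher and 4 lower by 2-fold. Pearson's r between the groups was 0.988 across tested genes without small RNA genes, where genes are not independent replicates.

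The split into higher and lower genes depended on the scaling. The median log2 ratio of tested genes was −0.07 as deposited and 0.16 after upper-quartile scaling. Part of the upper-quartile scaling comes from which genes are above 0 in the deeper CXCL8 sample. The ratio of the quartiles was 0.840, and 0.940 over genes above 0 in both groups. At 1.5-fold, 48.3% of the differing genes were higher as deposited, 62.9% (346 higher, 204 lower) after centring on the median, and 83.4% (698 higher, 139 lower) after upper-quartile scaling. Among genes with at least 5 FPKM in both groups these shares were 51.9%, 75.4% (86 higher, 28 lower) and 96.0% (262 higher, 11 lower). At 2-fold, 27.8% were higher as deposited, 32.8% (41 higher, 84 lower) after centring and 49.7% (71 higher, 72 lower) after upper-quartile scaling. After upper-quartile scaling 21 of the 189 named genes, all lower after CXCL8, no longer reached 1.5-fold, among them RELB, IL33, DLL4, NOV, CLDN5, GJA4, EFNB2, HEY1, IFIT5, NR4A1 and DUSP5, whereas VCAM1, HMOX1 and AQP1 did. List medians moved with the scaling: 21 of 29 were below 0 as deposited, 18 after centring and 2 after upper-quartile scaling. The percentile of a list among random lists measures its position relative to other genes of like expression.

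Of 33 gene lists fixed before the data were examined, 29 had at least 5 measured members, and 8 had a median outside the central 95% of the medians of 10000 expression-matched random lists. If genes varied independently, chance would place 1.45 of 29 outside it. Genes of a list vary together and some lists share genes, so 8 against 1.45 is not a test of the treatment. Of the 8 lists, 2 lay below the range and 6 above.

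**Figure D1:**
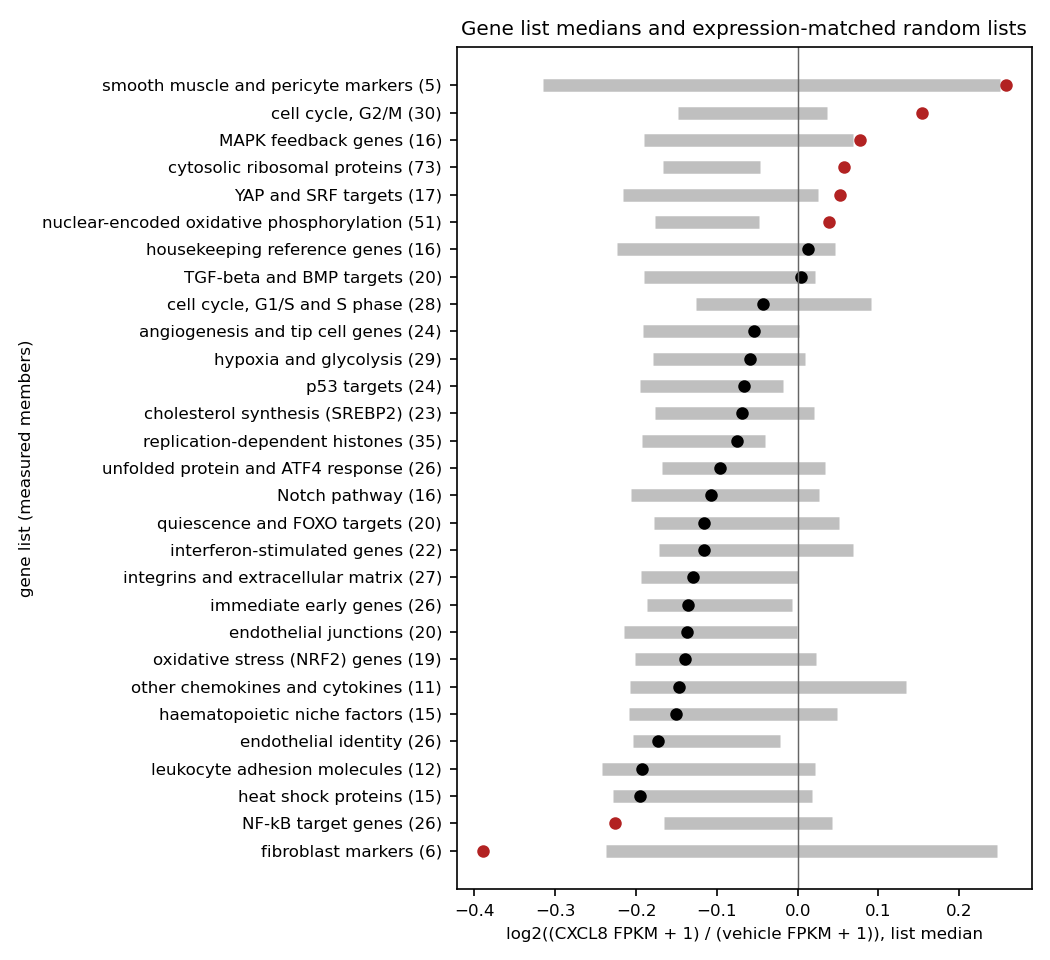
Median log2 ratio of FPKM + 1, CXCL8 over vehicle, of each gene list with at least 5 measured members (x axis; number of measured members in parentheses on the y axis). Grey bars span the central 95% of 10000 expression-matched random lists, and red points mark the 8 lists outside their bar, with fibroblast markers and NF-kB target genes on the lower side.

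Few ligand and receptor genes of the CXCL8 system passed the expression filter. Without fragment counts, a listed 0 does not show that a transcript was absent. CD99 was also listed at 0 in both groups, but the reason was not tested, so its 0 does not bear on the receptors. Endogenous CXCL8 transcript (listed under its older symbol IL8) stood at 23.2 FPKM after CXCL8 and 19.9 in vehicle, a log2 ratio of 0.21. CXCR1 was listed at 0 in both groups. CXCR2 was listed at 0 in vehicle and at 0.049 FPKM after CXCL8, and ACKR1 (listed as DARC), the atypical chemokine receptor, at 0.064 and 0.31 FPKM. The other measured ligands CXCL2 and CXCL1 had ratios of 0.22 and 0.12, and CXCL3, below the expression filter and named after its values were seen, stood at 0.27 against 0.83 FPKM. With 3 measured members, 0 of them past 1.5-fold, this list was too short for a percentile.

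NF-kB target genes, which respond to inflammatory signals, had a median log2 ratio of −0.23, at percentile 0.10 of random lists. Of 26 measured members, 0 were higher and 2 lower by 1.5-fold: VCAM1, and RELB, an NF-kB subunit, at 10.4 against 16.6 FPKM. CX3CL1, a membrane-bound chemokine, had a ratio of −0.54 and IER3, a stress response gene, −0.47. Of the 26 members 7 exceeded the median of all tested genes, among them CXCL2 (0.22), TNFAIP3 (0.14) and CCL2 (0.07). After upper-quartile scaling the median was −0.02 and the percentile 0.04, with VCAM1 alone lower by 1.5-fold, as after centring. By the mean of its members the list lay at percentile 3.26, inside the range of random lists. Fibroblast markers, the other list below the range, had a median of −0.39 at percentile 0.13, with 0 of 6 members past 1.5-fold. COL1A2 stood at 13.9 against 18.8 FPKM, COL3A1 at 6.16 against 8.46, LUM at 1.31 against 2.05 and DCN at 1.49 against 2.23; COL1A1, a major fibroblast collagen, was below the expression filter at 0.020 against 0.015 FPKM.

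Leukocyte adhesion molecules lay at percentile 9.93, with 0 of 12 members higher and 1, VCAM1, lower by 1.5-fold. The junctional molecule F11R had a ratio of −0.44, ICAM1, a ligand of leukocyte integrins, −0.37 with 13.1 against 17.2 FPKM, and SELE, the endothelial selectin, −0.28 with 9.56 against 11.9 FPKM. Haematopoietic niche factors lay at percentile 14.8, with 0 of 15 higher and 3 lower: VCAM1, the Notch ligand DLL4 at 18.5 against 28.6 FPKM, and NOV at 1.10 against 2.23 FPKM. This one-sided count did not hold under the other scalings, with 1 higher (TGFB1) and 1 lower (VCAM1) after centring, and 2 higher (TGFB1 and CXCL12) and 1 lower after upper-quartile scaling. As deposited, TGFB1 had a ratio of 0.53. KITLG, the ligand of the stem cell receptor KIT, stood at 17.3 against 16.6 FPKM, and CXCL12, a chemokine that retains blood stem cells, at 1.39 against 0.736 FPKM. Other chemokines and cytokines lay at percentile 10.8. Of their 11 members 0 were higher and 1 lower: IL33, a nuclear cytokine of endothelial cells, at 21.3 against 36.4 FPKM. CXCL11 had a ratio of 0.48 and IL15 −0.39; after upper-quartile scaling 1 member was higher and 0 lower. Interferon-stimulated genes lay at percentile 14.9, with 0 of 22 higher and 1 lower, IFIT5 at −0.62. IFIH1, ISG20 and GBP2 had ratios of −0.45, −0.43 and −0.41, and 0 members passed 1.5-fold under either other scaling.

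Endothelial identity genes lay at percentile 8.83, with 2 of 26 members higher and 1 lower by 1.5-fold. ENG, a co-receptor of the TGF-beta family, stood at 85.8 against 47.2 FPKM (ratio 0.85), and SOX18, an endothelial transcription factor, at 43.6 against 27.4 FPKM (0.65). CLDN5, the main claudin of endothelial tight junctions, stood at 97.6 against 158 FPKM (−0.69), and CLEC14A had a ratio of −0.46. KDR, CDH5, PECAM1 and VWF had ratios of −0.06, −0.07, −0.15 and −0.11, close to the median of all genes, and all 4 were above 0 after upper-quartile scaling, KDR also after centring.

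Notch pathway genes had 0 of 16 members higher and 4 lower by 1.5-fold, although the list's median lay inside the random range, at percentile 43.2. The 4 were GJA4, which encodes the arterial gap junction protein connexin 37, at 61.7 against 104 FPKM (−0.74), the arterial ephrin EFNB2 at 52.8 against 86.6 FPKM (−0.70), the Notch target HEY1 at 4.82 against 8.45 FPKM (−0.70), and DLL4 (−0.60). After centring 3 of them passed 1.5-fold and after upper-quartile scaling 0. Endothelial junction genes lay at percentile 30.5, with 0 of 20 higher and 2 lower, GJA4 and CLDN5; GJA5 had a ratio of −0.57, and after upper-quartile scaling 0 passed 1.5-fold. Angiogenesis and tip cell genes lay at percentile 81.6, with 0 of 24 higher and 1 lower, DLL4. VEGFC, ADAMTS1 and MMP14 had ratios of −0.52, −0.49 and −0.49. After centring 0 of this list passed 1.5-fold, and after upper-quartile scaling 1 was higher and 0 lower.

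**Figure D2:**
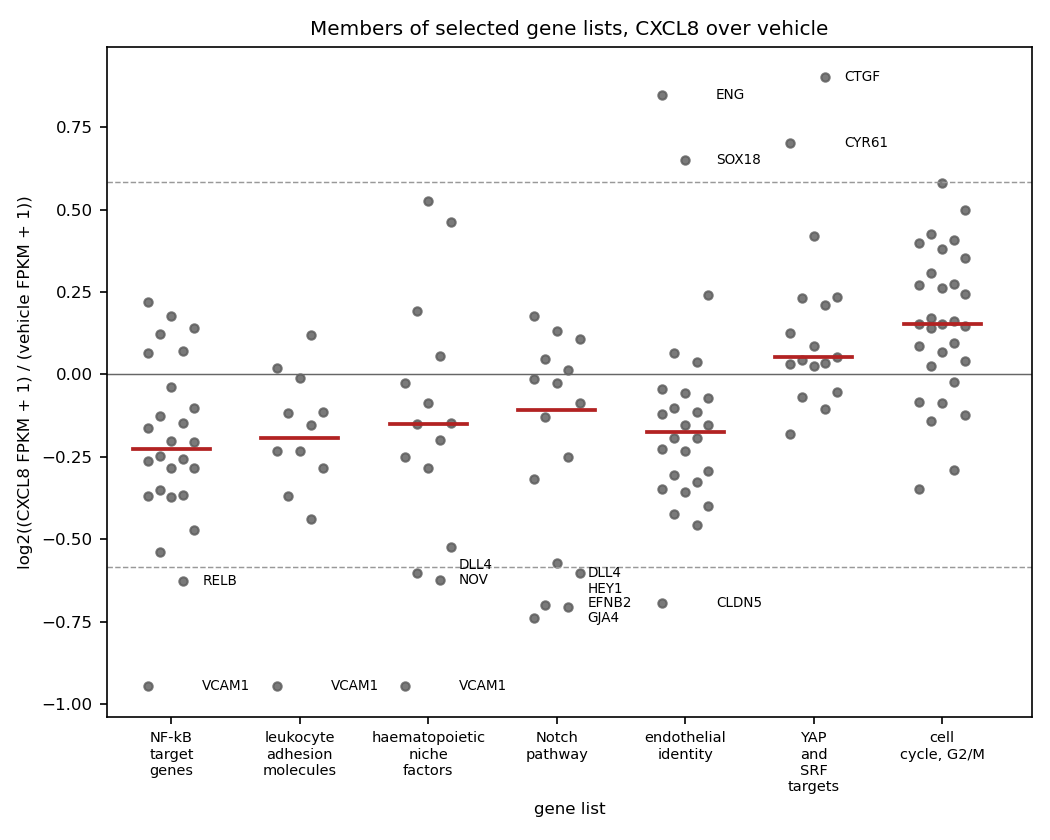
Log2 ratio of FPKM + 1, CXCL8 over vehicle (y axis), of each measured member of 7 selected gene lists (x axis), with 1 point per gene and a red line at the list median. Dashed lines mark 1.5-fold; VCAM1 at −0.95 and CTGF at 0.90 are the members farthest from 0, and the Notch pathway has 4 members below the lower line.

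YAP and SRF targets, transcribed in response to cell tension and actin dynamics, lay at percentile 99.1, with 2 of 17 members higher and 0 lower by 1.5-fold. These were CTGF (0.90) and CYR61 (0.70), both secreted matricellular proteins; ACTA2 had a ratio of 0.42 and AXL 0.24. By the mean of its members the list lay at percentile 97.31, just inside the range. ACTA2 is also among the smooth muscle and pericyte markers, which lay at percentile 97.8 with 0 of 5 members past 1.5-fold; ABCC9 stood at 5.39 against 3.41 FPKM, NOTCH3 at 1.18 against 0.820 and SMTN at 15.2 against 17.6, and RGS5, the most abundant, at 98.3 against 101.9 (−0.05). That list fell inside the range under 4 alternatives. TGF-beta and BMP targets lay at percentile 95.3, with 2 of 20 higher and 2 lower: ID2, a BMP-responsive inhibitor of transcription factors, at 12.9 against 6.38 FPKM and CTGF on one side, BMPER at 1.16 against 3.21 FPKM and HEY1 on the other. Integrin and extracellular matrix genes lay at percentile 25.1, with 1 of 27 higher, the collagen cross-linking enzyme LOX at 16.7 against 10.6 FPKM, and 0 lower; LAMA5 had a ratio of 0.50 and COL18A1 −0.48.

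Immediate early genes lay at percentile 21.2, with 2 of 26 higher and 2 lower by 1.5-fold. The higher members were CTGF and CYR61, and the lower ones NR4A1 at 1.14 against 2.36 FPKM and DUSP5, a phosphatase that acts on ERK, at 13.2 against 21.0 FPKM. After upper-quartile scaling 3 were higher and 0 lower. MAPK feedback genes had a median of 0.08 at percentile 98.2, with 0 of 16 higher and 1 lower, DUSP5; IER3, SPRED1 and DUSP4 had ratios of −0.47, −0.42 and −0.35, and 0 passed 1.5-fold under either other scaling. The direction of this list turned with the expression filter: with at least 5 FPKM in 1 group its median was −0.18 at percentile 13.72.

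Genes of the G2 and M phases had a median of 0.15, above all 10000 random lists. Of 30 members 24 exceeded the median of all tested genes, and 0 passed 1.5-fold as deposited and 6 after upper-quartile scaling, all higher. CENPA, the centromeric histone, stood at 4.88 against 2.93 FPKM (0.58), and the proliferation marker MKI67 at 3.21 against 1.98 FPKM (0.50). The mitotic kinases BUB1 and PLK1 had ratios of 0.43 and 0.41. Genes of G1/S and S phase lay at percentile 38.0, with 1 of 28 higher, the nucleotide synthesis enzyme TYMS (0.62), and 0 lower; CHAF1A and POLA1 had ratios of −0.45 and −0.44. Replication-dependent histones lay at percentile 85.3, with 0 of 35 higher and 4 lower: HIST1H4C, HIST1H4E, HIST1H4D and HIST1H2BB, with ratios from −0.63 to −0.60. None of the 4 reached 1.5-fold after centring or upper-quartile scaling, which gave 0 and 1 higher histone genes.

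Cytosolic ribosomal proteins had a median of 0.06 and nuclear-encoded oxidative phosphorylation genes 0.04, both above all 10000 random lists. Among 73 ribosomal protein genes 1 was higher by 1.5-fold, RPL21, which has near-identical copies, and 0 were lower. RPL28 and RPS15A had ratios of 0.44 and 0.38. Among 51 oxidative phosphorylation genes 0 passed 1.5-fold. ATP5J had a ratio of 0.53 and NDUFV1 −0.37, and by the mean of its members this list lay at percentile 89.9.

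Stress and metabolic lists lay inside the range of random lists. Oxidative stress genes of the NRF2 programme lay at percentile 19.8, with 1 of 19 higher and 1 lower: the metallothionein MT1X (0.59) and HMOX1. MT2A stood at 219 against 147 FPKM and FTH1, the ferritin heavy chain, at 492 against 345. Heat shock proteins lay at percentile 6.58 with 0 of 15 past 1.5-fold; DNAJA1, HSP90AB1 and BAG3 had ratios of −0.50, −0.46 and 0.40. With at least 5 FPKM in 1 group this list lay at percentile 2.34, outside the range. The unfolded protein and ATF4 response lay at percentile 33.6 with 1 of 26 higher, the transcription factor CEBPB at 8.32 against 4.61 FPKM, and 0 lower. Cholesterol synthesis (23 members), hypoxia and glycolysis (29), p53 targets (24) and quiescence and FOXO targets (20) lay at percentiles 64.2, 74.2, 83.6 and 21.2, each with 0 members past 1.5-fold. In the order of these lists, LSS had a ratio of −0.39, DDIT4 −0.38, FAS 0.44 and INSR −0.50.

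Housekeeping genes lay at percentile 93.3, with 3 of 16 higher and 0 lower by 1.5-fold. Among the higher members, HPRT1 and POLR2A had ratios of 0.79 and 0.65, whereas ACTB and B2M stood at 0.15 and 0.04 and GAPDH at −0.06, the last above 0 under both other scalings. Markers of other cell types were few: 2 leukocyte markers, CD68 and LAPTM5 (−0.11 and −0.09), 4 epithelial markers with 1 lower, KRT19 at 0.70 against 2.0 FPKM, and 0 erythroid or platelet markers.

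Of the 24 largest differences by the fixed rule of size, 9 were read-through genes (3 higher, 6 lower) and 3, RPL21, H3F3A and RNF5, have near-identical copies, so that the values of these 12 are uncertain. The value of DYX1C1 is uncertain as well, since this gene is part of the read-through gene DYX1C1-CCPG1. The 2 had opposite ratios, 1.49 for DYX1C1 and −1.86 for DYX1C1-CCPG1. The 12 largest on the higher side were RPL21 (5.86), H3F3A (3.49), SLMO2-ATP5E, NARR, INO80B-WBP1, LOC100144603, SNURF, DYX1C1, ANKHD1-EIF4EBP3, ATXN2L, KANSL1-AS1 and SRRM2 (1.19). SLMO2-ATP5E and NARR were listed at 0 in vehicle. SRRM2, which encodes a splicing factor, stood at 17.7 against 7.2 FPKM. The 12 largest on the lower side were RPL36A-HNRNPH2 (−2.79), SNHG9 (−2.72), RNF5 (−2.24), DYX1C1-CCPG1, ZNF664-FAM101A, PMF1-BGLAP, RPPH1, CDK3, C7orf66, PCCA-AS1, STX16-NPEPL1 and C15orf38-AP3S2 (−1.29). RPL36A-HNRNPH2, ZNF664-FAM101A, C7orf66 and PCCA-AS1 were listed at 0 after CXCL8. Among small RNA genes the 3 largest differences were SNORD68, listed at 0 after CXCL8 against 39446 FPKM, SNORD24, listed at 0 in vehicle against 39442 FPKM, and SNORD113-4, listed at 0 after CXCL8 against 27702 FPKM.

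A further ranking, chosen after the values were seen, took genes with at least 5 FPKM in both groups and left out small RNA genes, RMRP, RPPH1 and read-through genes. On the lower side were HMOX1, the water channel AQP1 at 10.4 against 23.1 FPKM (−1.08), the apolipoprotein L gene APOL3 at 13.4 against 28.0 (−1.01), the secreted glycoprotein gene STC1 at 8.7 against 18 (−0.97), and GUCY1A3, a subunit of the nitric oxide receptor guanylate cyclase, at 10.9 against 22.0 (−0.94). TNFRSF1B, the type 2 tumour necrosis factor receptor, and the transporter ABCG2 had ratios of −0.76 and −0.75. On the higher side, besides SRRM2, CTGF, ID2 and ENG, were LY96, which encodes the TLR4 co-receptor MD-2, at 33.4 against 16.8 FPKM (0.96), the transcription factor CREB3L2 at 15.5 against 7.68 (0.92), the nuclear RNA MALAT1 at 1015 against 537 (0.92), and ZFP36L1, an mRNA decay factor, at 20.7 against 10.9 (0.87). TNFRSF1B and ABCG2 were below 1.5-fold after upper-quartile scaling.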

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

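The GC content and length correction, random lists without small RNA genes, upper-quartile scaling of lists, lists without their most extreme member or without shared members, and counts with at least 5 FPKM in both groups or without read-through genes were chosen only after the data were seen. The number of genes higher by 2-fold, 35, became 128 with a pseudocount of 0.1, 18 with 5, 71 after upper-quartile scaling, 21 without small RNA genes and 6 with at least 5 FPKM in both groups, small RNA genes kept. The number lower, 91, became 156 with a pseudocount of 0.1, 22 without small RNA genes and 54 with at least 5 FPKM in both groups. A larger pseudocount draws every ratio toward 0 by construction, and the stricter filters test fewer genes. By the mean of members, the NF-kB list moved from percentile 0.10 to 3.26, YAP and SRF targets from 99.1 to 97.31, oxidative phosphorylation from 100 to 89.9 and MAPK feedback genes from 98.2 to 59.62. The MAPK list reversed to percentile 13.72 with at least 5 FPKM in 1 group. Smooth muscle and pericyte markers moved from percentile 97.8 to 93.0 with a pseudocount of 5, 94.5 by the mean, 95.09 after upper-quartile scaling and 66.14 after the GC and length correction. For these lists the cause was not tested. The lists of G2 and M phase, ribosomal protein and fibroblast genes stayed outside the range under each alternative that gave them a value; the 2 lists of other cell types had too few members for the filter of 5 FPKM, and smooth muscle and pericyte markers also without their most extreme member. Inside the range as reported but outside it under 1 alternative each were adhesion molecules (1.24) and histones (98.31) after the GC and length correction, and TGF-beta and BMP targets (98.94) and heat shock proteins (2.34) with at least 5 FPKM in 1 group. Among the 189 named genes, upper-quartile scaling took 21 below 1.5-fold and 23 above it, centring 9 and 6, a pseudocount of 5 took 31 below and one of 0.1 took 14 above. Centring cannot change a percentile. A replicate-based fit, leaving out a replicate and the submitters' own calls were not run, since the table holds 1 value per gene and group and no p-values. No paired analysis was possible because each group has 1 value per gene. Depth limits low genes most, as 1915 genes were listed at 0 in the shallower vehicle sample alone.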

Other observations

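All tests below were chosen after the values were seen. Some had predictions that were fixed before their own results were known. These were the GC content and length tests of the NF-kB and GIMAP genes and the arterial against venous test. The lists of GIMAP, arterial, venous, snoRNA host and nuclear long non-coding genes were likewise chosen after the values were seen, so their positions are not independent evidence.

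The GIMAP family, small GTP-binding proteins found in lymphocytes and endothelium, had a median log2 ratio of −0.50, below all 10000 random lists. Of 6 measured members 0 were higher and 2 lower by 1.5-fold: GIMAP1 at 11 against 19.1 FPKM and GIMAP7 at 28.5 against 46.3 FPKM. GIMAP6 stood at 47.8 against 69.2 FPKM and GIMAP8 at 20.1 against 28.3 FPKM. After upper-quartile scaling 0 members passed 1.5-fold. A trend with GC content or transcript length was tested as a source of this shift, and the family stayed at percentile 0 after the correction. A difference between the cultures remains open.

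Nuclear long non-coding RNAs had a median of 0.28 at percentile 99.9, with 3 of 7 members higher and 0 lower by 1.5-fold. MALAT1 stood at 1015 against 537 FPKM, MEG3 at 58.2 against 34.4 FPKM and NEAT1, the scaffold of paraspeckles, at 121 against 78.1 FPKM. TUG1 had a ratio of 0.28.

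Because GJA4, EFNB2, HEY1 and DLL4 mark arterial endothelium and were among the lower genes, a shift away from arterial expression was tested as a hypothesis. The median of 15 arterial genes was −0.21 (0 higher and 4 lower by 1.5-fold, 0 lower after upper-quartile scaling, percentile 3.10) and that of 6 venous genes −0.05 (0 past 1.5-fold, percentile 78.7). NR2F2, a regulator of venous identity, had a ratio of 0.32. TEK and EPHB4, also on the venous list, had −0.42 and −0.35, and TEK is on the endothelial identity list too. The gap of −0.16 was reached in 16.56% of random reassignments of the 21 genes, so the prediction of under 5% was not met. With 6 venous genes and 1 value per gene and group, this does not decide whether there was a shift.

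NF-kB target genes lay at percentile 0.10 of random lists. A trend with GC content or transcript length as the whole source is argued against, since the list stayed at percentile 0.28 after that correction. Fewer endothelial cells in the CXCL8 cultures were predicted to raise fibroblast markers, but these lay at percentile 0.13. COL1A2, the highest, stood at 13.9 FPKM after CXCL8, and COL1A1 at 0.020 FPKM. Smooth muscle and pericyte markers lay at 97.8, a position inside the range under 4 alternatives. RGS5, the most abundant of these at 98.3 FPKM, had a ratio of −0.05. These markers cannot decide the question, since only cell types present in the cultures would rise. With COL1A1 so low, it is also unclear whether the fibroblast list reports fibroblasts. A difference between cultures or samples unrelated to CXCL8 cannot be told apart from an effect of CXCL8, since there is 1 value per gene and group. Lower NF-kB target transcription 6 h after CXCL8 is a hypothesis that these data leave open.

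Small RNA genes above 0 in both groups were mostly lower after CXCL8. Medians were −0.62 for 37 SNORD genes (24 lower), −0.85 for 76 SNORA genes (72 lower), −0.63 for 20 SCARNA genes (18 lower) and −0.76 for 4 RNU genes (3 lower), and RMRP and RPPH1 had ratios of −0.91 and −1.50. For SNORA genes, lower expression of their host genes as the whole source is argued against: the 51 annotated hosts of 63 of the 76 had a median of −0.0079 (quartiles −0.12 and 0.22), and of 43 SNORA genes lower by 1.5-fold 1 had a host as much lower, SNORA78 in SNHG9. For SNORD and SCARNA genes hosts were found for 63.2% of 57, under the 80% needed for a test of the class, so this is open; these hosts had a median of −0.11 (quartiles −0.18 and 0.03), and of 22 such genes lower by 1.5-fold 0 had a host as much lower. Poorer recovery of short RNA and a change of small RNAs in the cells cannot be told apart, since both leave longer transcripts alike, such as 74 mRNAs longer than 350 nt and up to 700 nt with a median of 0.042; VTRNA1-1 (1.39) and 12 MIR genes (median 0.13) were not lower.

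Of 16 snoRNA host genes listed by hand, a list without SNHG9, 1 was higher and 0 lower by 1.5-fold. The median was 0.20, above all 10000 random lists, and SNHG12 stood at 16.7 against 10.3 FPKM. This list does not stand for host genes as a class. The annotated hosts had medians of −0.0079 for SNORA genes and −0.11 for SNORD and SCARNA genes.

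Read-through genes were often among the largest ratios. At least a 2-fold difference was found in 29.3% of 41 read-through genes against 0.26% of 11941 other genes without small RNA genes. DYX1C1-CCPG1 was lower (−1.86) and its part DYX1C1 higher (1.49), and INO80B-WBP1 was higher (1.83) and its part INO80B lower (−0.86). In contrast, SLMO2-ATP5E (2.90) and its part ATP5E (0.30) were both higher. Reads divided differently between overlapping models cannot be told apart from an effect of CXCL8 on these models: their summed FPKM decides nothing, since in 0 of 12 loci could the read-through gene alone move the sum by 1.5-fold. The same holds for division of reads between RPL21, H3F3A or RNF5 and their near-identical copies. There the gene alone could move the sum by at most 0.30 on the log2 scale. RPL21 stood at 58.1 against 0.021 FPKM and its copy RPL21P28 at 1548 against 1499. H3F3A stood at 10.4 against 0.014 FPKM and its copy H3F3AP4 at 403 against 410. RNF5 stood at 0.97 against 8.30 FPKM and its copy RNF5P1 at 36.6 against 29.6.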
